A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

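Whole-cell RNA of 6 Saccharomyces cerevisiae strains was measured by RNA sequencing, with 1 library per strain, so groups hold 1 library each. Reads were handled with TopHat2 2.0.6, Cuffdiff 2.1.1 and the sacCer3 genome build, per the submitters' processing notes. The authors deposited 1 FPKM value per feature and library, with a lower and an upper confidence bound, for 7126 features, and each gene name had 1 row. FPKM divides fragments by feature length and by a library total, so it is a relative measure, and a large group such as ribosomal protein genes moves the values of the rest. A separate deposited table gives the authors' own p-value and q-value for each of the 15 pairs of libraries; per the file headers a gene is marked significant at q up to 0.05. Those p-values come from 1 library per strain, so they hold no spread between replicates, and they are quoted only as the authors'. The number of per-sample columns left without a sample was 0.

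The depth of each library is unknown. Of the bounds worth 0.5 to 50 fragments, 87.7% lie within 0.02 of a whole number on a scale of 5624332 fragments common to all libraries, on which 1 FPKM in a gene of 1000 nt is 5.62 fragments. The FPKM values themselves lie on that grid in 4.03% of cases, where chance gives 4%, so no fragment counts were recovered and no count test was run. Short features are inflated: the median ratio of FPKM to the midpoint of its own interval was 19.1 at 100 to 150 nt, 6.23 at 150 to 200 nt, 2.32 at 200 to 300 nt and 1.02 at 300 to 500 nt. Of the features, 1420 share a locus with another in the table, and ribosomal protein paralogs, PHO11 and PHO12, Ty elements and overlapping pairs such as STE3 with YKL177W and HIS3 with YOR203W share reads or sequence, so their values are uncertain. Whether counting used the strand is not given in the sources used here. An exact 0 can be a failed estimate, so it is reported only as listed at 0. RefSeq coordinates matched the deposited ones for 5227 of 5237 nuclear features alone at their locus (99.8%).

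From these values log2((FPKM + 1)/(FPKM + 1)) was computed with a pseudocount of 1 for the 5738 features with a mean FPKM of at least 1 over the 6 libraries. Features at least 2-fold apart were counted in each direction for 5 comparisons, the mrpl16 rho-minus library against the rho-plus library and 4 phosphatase deletions against the mrpl16 rho-minus library. With 1 library per side there is no test, and no p-value was computed. For 38 gene lists the median log2 fold was placed among 10000 random lists matched over 20 bins of mean expression. The random lists were drawn from all kept features, members of the list itself included. A list was said to stand apart when it was among the lowest or the highest 2.5%. Lists that stood apart numbered 12 high and 5 low for the mtDNA comparison, 12 and 9 for sit4, 3 and 10 for sap155 sap190, 4 and 14 for sap4 sap190 and 8 and 9 for pph21 pph22. The return towards the rho-plus level and the resemblance of the deletions were compared with 100 simulations of libraries without any effect, because the comparisons share the reference library.

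The comparisons, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule named the 7 deleted genes; per comparison the 12 highest and 12 lowest folds among features with at least 10 FPKM in the higher library; the 4 members of each list with the largest folds; and CIT2, DLD3, PDR5, PDR15, FET3, FIT2, HSP12, CLN2 and PHO84. Of the 120 features that the second part named, 106 were shorter than 300 nt, where FPKM is inflated, so the text names genes of at least 300 nt by the same rule. That length limit was chosen after the values were seen, as was naming RPL3, the pheromone and marker genes and the genes the authors' table marked.

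Alternatives were pseudocounts of 0.1 and 5, no expression minimum or a mean FPKM of at least 10, centring, scaling to the same sum or the same upper quartile, the sap4 sap190 library as reference, the mean of the 5 libraries labelled rho-minus, a 4-fold threshold and disjoint libraries. Features of at least 300 nt, non-overlapping deposited intervals, the comparison without mating-type genes, the choice of genes through each other library and the same-sum and upper-quartile scales for gene lists, also against the rho-plus library, and the comparison without features at 0 in either library were added after seeing the data. The scripts were tested on simulated data for the sit4 comparison, with 5738 genes and a noise SD of 0.272 on the log2 scale. That SD came from the median absolute deviation of the folds between the sap155 sap190 and sap4 sap190 libraries. It gives little weight to extreme folds and is not a spread between replicates. Of 50 genes planted at each log2 fold, 7 were called at 0.5, 47 at 1.5, 50 at 2 and 50 at 3, with 48 of 5538 unchanged genes called. Of 200 unchanged lists 11 stood apart, and of 50 lists shifted by 0.5 all 50 did. The noise was drawn for each gene separately and the lists at random. Genes of a real list can vary together, so how often such lists stand apart without an effect was not tested. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.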

Results

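RNA from whole cells of 6 strains of the budding yeast Saccharomyces cerevisiae was sequenced, with 1 library per strain. Cells with intact mitochondrial DNA are called rho-plus, and cells that have kept only a damaged part of it are called rho-minus. The rho-plus library stood against 5 libraries labelled rho-minus, all from strains without MRPL16, which encodes a protein of the large subunit of the mitochondrial ribosome. The mrpl16 rho-minus library served as the reference for the other 4, whose strains also lacked SIT4, SAP155 and SAP190, SAP4 and SAP190, or PPH21 and PPH22. SIT4 encodes a phosphatase related to PP2A, the SAP genes encode proteins that bind Sit4, and PPH21 and PPH22 encode the main catalytic subunits of PP2A. The stated interest of the series is whether deleting these phosphatase genes reverses the consequences of damaged mitochondrial DNA.

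With 1 library per strain no difference has a replicate check, and every statement compares libraries rather than strains. The deposited values were FPKM, and the read depth of each library is unknown, because the confidence bounds deposited beside the FPKM lie on 1 common scale of 5624332 fragments. Log2 folds are log2((FPKM + 1)/(FPKM + 1)), a scale that understates the difference of low genes, and "higher" or "lower" in a count means at least 2-fold apart on it. A value of exactly 0 is written as listed at 0, and no fold is given for a single gene listed at 0. Such genes still enter the counts and list medians through the added 1. The percentile beside a gene list places its median among 10000 random lists of the same size matched on mean expression, as a description of these libraries. A list among the lowest or the highest 2.5% is said to stand apart. Genes of a list can vary together between cultures, which random lists leave out, so a list can stand apart without an effect of the deletion. The sum of FPKM was 4759110 in the rho-plus library, 2270044 in the reference, 2865848 in the sit4 library, 3425900 in the sap155 sap190 library, 2997955 in the sap4 sap190 library and 2741841 in the pph21 pph22 library. Genes for cytosolic ribosomal proteins made up 57.2% of the sum in the rho-plus library and 43.8% to 47.2% in the others. With every library rescaled to the same sum, the median log2 fold of all genes moved from 0.02 to 0.90 in the comparison of the reference with rho-plus, from -0.01 to -0.30 for sit4 and from 0.02 to -0.48 for sap155 sap190; the upper-quartile scale moved the last to -0.11. For sap4 sap190 it moved from 0.02 to -0.31 on the same-sum and to -0.13 on the upper-quartile scale, and for pph21 pph22 from -0.03 to -0.26 on the same-sum and to 0.06 on the upper-quartile scale. The upper-quartile scale moved the sit4 median to 0.04. List medians moved with that shift, and 84 of the 86 lists that stood apart still did so on the same-sum scale. A change of scale moves a list and its matched lists alike, apart from the effect of the added 1. That count is therefore no independent check, and the same holds wherever a list is said to stand apart on another scale.

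The deleted genes matched the genotype labels. MRPL16 (YBL038W, chromosome II, 146187 to 146885 in sacCer3) had 14.6 FPKM in the rho-plus library and was listed at 0 in the other 5. SIT4 was listed at 0 in the sit4 library and had 5.95 to 21.9 FPKM elsewhere. SAP190 was listed at 0 in both sap190 libraries and had 3.38 to 5.54 FPKM elsewhere. SAP4 was listed at 0 in the sap4 sap190 library and had 0.640 to 2.76 FPKM elsewhere. SAP155 had 0.255 FPKM in the sap155 sap190 library against 1.85 to 4.47 elsewhere, a low but nonzero value. PPH21 and PPH22 were listed at 0 in the pph21 pph22 library, with at least 14.3 and 18.1 FPKM elsewhere.

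Transcripts of the mitochondrial genome differed among the libraries labelled rho-minus. Rho-minus cells keep part of the mitochondrial DNA, so such transcripts do not by themselves contradict the label. The reference listed every such feature at 0, and whether its cells kept any mitochondrial DNA cannot be told from these values. Over 23 mitochondrial features of at least 300 nt, the summed FPKM was 40.1 in the rho-plus library and 0 in the reference, but 47.4 in the library labelled sit4 rho-minus. The sums were 12.9 in the sap155 sap190 library, 1.40 in the sap4 sap190 library and 4.71 in the pph21 pph22 library. COX1, which encodes a subunit of cytochrome c oxidase, had 4.19 FPKM in the rho-plus library and 3.65 in the sit4 library. Of the 10 features with at least 0.5 FPKM in the rho-plus library, 10 reached that level in the sit4 library. In the sap155 sap190, pph21 pph22 and sap4 sap190 libraries 6, 4 and 0 did. The 10 are the rRNA genes, COX1, and AI and BI features, named for introns of COX1 and COB. They are not independent, in this count or in the sums. ATP6 and COX2 had 0.453 and 0.445 FPKM in the rho-plus library and were listed at 0 in the sit4 library. AI3 and BI3 were listed at 0 in the rho-plus library and had 0.633 and 1.38 in the sit4 library. Directions drawn from the library labelled sit4 rho-minus therefore compare a library with mitochondrial transcripts to a reference without them. The same limit applies to the other 3 phosphatase libraries, at 32.2% (sap155 sap190), 11.7% (pph21 pph22) and 3.48% (sap4 sap190) of the rho-plus sum.

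**Figure D1:**
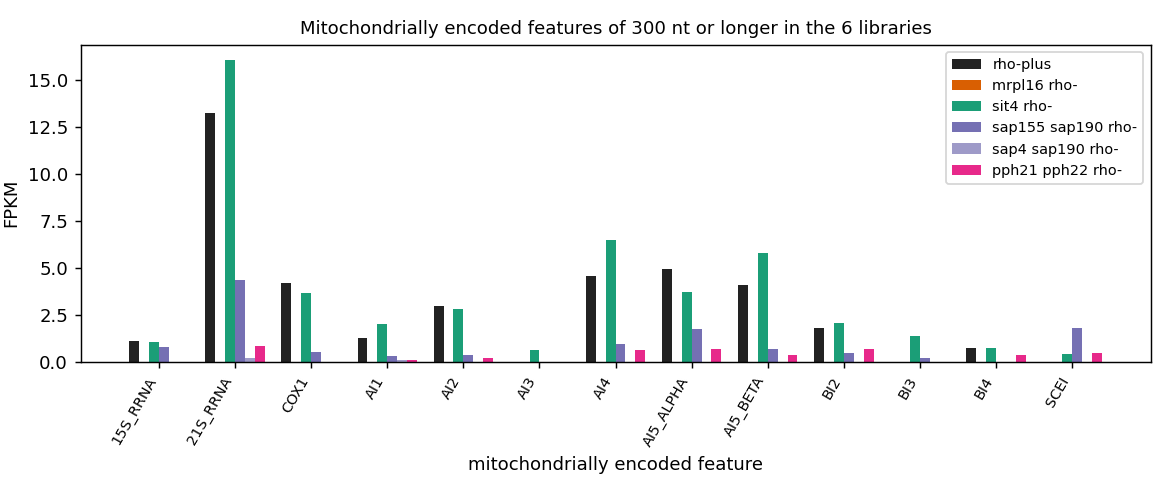
FPKM of mitochondrially encoded features in the 6 libraries, 1 library per strain with no error bars. Only features of at least 300 nt that reached 0.5 FPKM in at least 1 library are drawn, which leaves out ATP6, COB, COX2, COX3 and VAR1. Over 23 features, drawn or not, the library labelled sit4 rho-minus sums to 47.4 FPKM, beside 40.1 in the rho-plus library and 0 in the mrpl16 rho-minus reference.

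Mating type and marker genes also separated the libraries. The rho-plus library had the transcripts of a MATa strain, with 822 FPKM of the receptor gene STE2 and 87.9 of HMRA1, and MF(ALPHA)1 was listed at 0. The 5 libraries labelled rho-minus had 5046 to 16939 FPKM of the pheromone gene MF(ALPHA)1 and at most 7.15 of STE2. The uracil gene URA3 was listed at 0 in the rho-plus library and had 20.3 to 230 FPKM in the others. HIS3 was listed at 0 except in the sit4 (26.9 FPKM) and pph21 pph22 (83.6 FPKM) libraries. LEU2 (8.15 FPKM) and TRP1 (16.7 FPKM) were above 0 only in the pph21 pph22 library, where LYS2 was listed at 0.

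The comparison of the mrpl16 rho-minus reference with the rho-plus library asks how cells differ once mitochondrial DNA is damaged. Targets of the retrograde pathway, which signals mitochondrial state to the nucleus, were higher in the reference for 6 of 7 members, none was lower and 1 was neither (median log2 fold 2.47, percentile 100). The peroxisomal citrate synthase gene CIT2 (chromosome III, 120946 to 122328) had 25.4 FPKM in the rho-plus library and 218 in the reference. The mitochondrial isocitrate dehydrogenase gene IDH1 had 54.6 and 676, and the aconitase gene ACO1 had 128 and 713. Of 24 genes of the iron regulon, controlled by Aft1 and Aft2, 15 were higher, 1 was lower and 8 were neither (1.38, percentile 100). The cell wall mannoprotein genes FIT2 and FIT3, whose products retain siderophores, had 25.1 and 10.1 FPKM in the rho-plus library and 2057 and 1567 in the reference. The TIS11 gene, for an RNA-binding protein that lowers iron-consuming transcripts, had 5.01 and 108.

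Drug resistance targets of Pdr1 and Pdr3 were higher for 4 of 14 members and lower for 0 (0.60, percentile 98.7), with the drug pump gene PDR5 at 17.3 and 91.6 FPKM and the RSB1 gene at 0.858 and 12.1. Phosphate genes controlled by Pho4 were higher for 12 of 17 (1.29, percentile 100), including the transporter gene PHO84 at 605 and 2957 FPKM. The general stress list of Msn2 and Msn4 targets had 12 of 25 members higher and 0 lower (0.99, percentile 100); the small heat shock protein gene HSP26 had 3.97 and 102 FPKM. The TCA cycle (5 of 15 higher, median 0.80), the mitochondrial ribosome (17 of 66 higher, 0.56), nitrogen catabolite repression targets (7 of 18 higher, 0.78) and vacuolar protease and autophagy genes (6 of 13 higher, 0.76) stood apart on the high side with 0 members lower. CIT1, ACO1, IDH1 and IDH2 are in both the TCA and the retrograde list, and HSP26 and HSP42 in both the general stress and the heat shock list. Such lists are not independent in any of the comparisons. The nuclear genes of the respiratory chain and ATP synthase did not stand apart: 0 of 37 were higher or lower (0.03, percentile 93.7). Amino acid biosynthesis genes controlled by Gcn4 were higher for 13 of 40 and lower for 2 (0.48, percentile 100). When the mean of the 5 libraries labelled rho-minus took the place of the reference, the Gcn4 median was -0.26, and Pdr1 and Pdr3 targets (0.08, percentile 50.7), nitrogen catabolite repression targets (0.34, percentile 97.1) and vacuolar genes (0.23, percentile 83.2) no longer stood apart. On that mean the retrograde, iron and general stress medians were 1.49, 0.59 and 0.50, which still stood apart, and the respiratory chain median was 0.27 at percentile 99.8. The Pdr1 and Pdr3 list also did not stand apart with a pseudocount of 5 (0.30), no expression minimum (0.29), a mean FPKM of at least 10 (0.78 over 4 members) or the same-sum scale (1.36), nor did the nitrogen list at a mean FPKM of at least 10 (0.62 over 4 members).

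Cytosolic ribosomal protein genes were lower in the reference for 109 of 136 members and higher for 0 (-1.43, percentile 0). Matched lists of highly expressed genes, which can hold ribosomal protein genes themselves, had a median of -1.09. On the same-sum scale only 2 of the 136 were lower and the median was -0.36. The list still stood apart on the low side because matched lists lay at -0.02. Ribosomal protein genes make up much of the sum that sets this scale, so it moves their median towards 0 in part by construction. RPL3, a ribosomal protein gene with no paralog, had 23774 FPKM in the rho-plus library and 8280 in the reference. Ribosome biogenesis genes had a median of -0.65 (8 of 42 lower, 0 higher), proteasome genes -0.60 (5 of 32 lower, 0 higher) and genes of the G1/S transition -0.43 (2 of 22 lower, 0 higher). All 3 lists stood apart on the low side. On the same-sum scale, which moved all genes to a median of 0.90, their medians were 0.31, 0.46 and 0.45, and all 3 still stood apart on the low side. With the mean of the 5 libraries labelled rho-minus, ribosome biogenesis genes did not stand apart (-0.12, percentile 14.9), while the G1/S median of -0.24 did. The pyrimidine genes URA1 (657 and 63.8 FPKM) and URA4 (177 and 38.1) were lower in the reference, beside URA3 listed at 0 in the rho-plus library. The cytosolic aldehyde dehydrogenase gene ALD6 was lower as well, at 220 and 40.8 FPKM.

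Mating-type genes differed by the widest medians of these lists: all 4 MATalpha-specific genes were higher (median 7.81, or 7.32 over the 3 not listed at 0 in either library) and all 7 MATa-specific genes lower (-5.76). Of 17 mating response genes, 7 were higher and 1 lower (0.93, percentile 99.98), among them AGA1 at 17.3 and 190 FPKM. In all, 639 genes of 5738 were higher and 452 lower, or 58.6% higher, against 2508 and 63 (97.55% higher) on the same-sum scale. Lower genes were the more numerous at a mean FPKM of at least 10, with 308 higher and 368 lower (45.6% higher), and with a pseudocount of 5, with 321 and 338 (48.7% higher). The deletion of MRPL16, the state of the mitochondrial DNA, the mating type and the URA3 marker differ together here and cannot be separated. The rho-plus library also has a provider number apart from those of the other 5 libraries. A difference in handling or sequencing therefore cannot be separated either, here or in any value set against rho-plus. The genes that the authors' deposited table marked lower in this comparison were 21S_RRNA, HMRA1 and the deleted MRPL16. Those marked higher included MF(ALPHA)1, SAG1 and URA3, so mating type and marker enter these calls. The authors' deposited table marked 11 genes higher and 3 lower, all with p = 5e-05 and q = 0.0223, including FIT2, FIT3, TIS11 and ARN2.

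The sit4 comparison asks what deleting SIT4 does in cells labelled rho-minus. Gcn4 targets were lower in the library labelled sit4 rho-minus for 36 of 40 members, higher for 0 and neither for 4 (median -2.23, percentile 0). ARG1 (chromosome XV, 219211 to 220473), for argininosuccinate synthase, had 853 FPKM in the reference and 4.61 in the sit4 library, with deposited bounds of 139 to 1560 and of 1.83 to 7.32. The vitamin B6 gene SNZ1 had 2269 and 8.50 FPKM, the carbamoyl phosphate synthase gene CPA2 had 210 and 6.06, and ARG4, for argininosuccinate lyase, had 401 and 9.67. HIS3, which was listed at 0 in the reference, had 26.9 FPKM in this library. The retrograde list was lower for 5 of 7 and higher for 1 (-2.09, percentile 0): CIT2 had 218 and 43.7 FPKM, ACO1 had 713 and 124 and IDH1 had 676 and 169. The higher member was the mitochondrial citrate synthase gene CIT1, at 58.1 and 135 FPKM.

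Iron regulon genes were lower in the library labelled sit4 rho-minus for 12 of 24 and higher for 0 (-0.92, percentile 0), with FIT2 at 2057 and 249 FPKM and FIT3 at 1567 and 69.6. Pdr1 and Pdr3 targets were lower for 6 of 14 and higher for 0 (-0.91, percentile 0.01); PDR5 had 91.6 and 7.35 FPKM, and its deposited bounds of 9.09 to 174 and of 2.39 to 12.3 overlapped. Mating response genes (7 of 17 lower, -0.87), MATalpha-specific genes (4 of 4 lower, -2.61), nitrogen catabolite repression targets (5 of 18 lower and 1 higher, -0.46), mitochondrial ribosome genes (5 of 66 lower, -0.27) and mitochondrial import genes (1 of 34 lower, -0.22) stood apart on the low side. The alpha-agglutinin gene SAG1 had 448 and 43.6 FPKM. Against the sap4 sap190 library instead of the reference, the iron regulon (-0.39, percentile 5.68), Pdr1 and Pdr3 targets (-0.14, percentile 26.9), nitrogen targets (-0.12, percentile 21.3) and mitochondrial import genes (-0.33, percentile 9.88) no longer stood apart; the retrograde and mitochondrial ribosome medians were -1.22 and -0.70 and still did. At a mean FPKM of at least 10, Pdr1 and Pdr3 targets (-0.63 over 4 members), nitrogen targets (-0.08 over 4 members) and import genes (-0.07) did not stand apart either.

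Nuclear respiratory chain and ATP synthase genes were higher in the library labelled sit4 rho-minus for 19 of 37 and lower for 0 (1.10, percentile 100), in the library that also held mitochondrial transcripts. The cytochrome c gene CYC1 had 77.5 and 715 FPKM, COR1 of complex III had 8.12 and 34.1, and COX6 of complex IV had 60.6 and 225. Phosphate genes were higher for 6 of 17 (0.55, percentile 99.97), with the acid phosphatase gene PHO5 at 38.8 and 610 FPKM. Glycolysis and fermentation (6 of 19 higher, 0.78), cell wall integrity targets of Rlm1 (8 of 21 higher, 0.50), ergosterol synthesis (5 of 25 higher, 0.51), phospholipid synthesis (3 of 14 higher, 0.77) and daughter-cell separation targets of Ace2 (3 of 11 higher, 0.77) stood apart on the high side with 0 members lower. Examples were the mannoprotein gene CWP1 at 19.4 and 152 FPKM, the sterol demethylase gene ERG11 at 162 and 427 and the inositol transporter gene ITR1 at 58.2 and 180. G1/S genes had a median of 0.46 with 0 of 22 members 2-fold apart, gluconeogenesis genes 0.37 (2 of 7 higher, 0 lower) and Yap1 targets 0.40 (3 of 19 higher, 2 lower). Ribosome biogenesis (0.29) and proteasome genes (0.28) also stood apart, and they still did at -0.01 and -0.04 on the same-sum scale, where all genes had a median of -0.30. Against the sap4 sap190 library, ribosome biogenesis genes stood apart on the low side (-0.45), gluconeogenesis genes no longer stood apart (0.31, percentile 85.6) and the cell wall median was 1.02. Gluconeogenesis genes also did not stand apart without an expression minimum (0.03), Yap1 targets with a pseudocount of 5 (0.23, percentile 96.3), or proteasome genes under those settings, a mean FPKM of at least 10 or without features at 0 in either library (percentiles 97.0 to 97.3).

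Counts for sit4 were 282 genes higher and 402 lower, or 41.2% higher, against 170 and 674 (20.1% higher) on the same-sum scale. Only 10 of the higher and 57 of the lower genes of at least 300 nt had deposited intervals that did not overlap those of the reference. The authors' deposited table marked 1 gene higher, the mitochondrial rRNA 21S_RRNA, and 10 lower, among them ARG1, ARG7, CPA2, SNZ1, GCV1, GCV2 and SIT4.

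The sap155 sap190 comparison asks what loss of this pair of Sit4-binding proteins does. General stress genes were lower for 16 of 25 members and higher for 0 (median -1.45, percentile 0): HSP26 had 102 FPKM in the reference and 21.6 in the sap155 sap190 library, and HSP12, another small heat shock protein gene, had 32.9 and 3.05. Heat shock genes controlled by Hsf1 were lower for 6 of 19 and higher for 0 (-0.68, percentile 0). HSP78, for a mitochondrial chaperone, had 16.1 and 1.49 FPKM, the disaggregase gene HSP104 had 17.2 and 2.87, and the Hsp90 gene HSP82 had 71.4 and 15.2. Ribosome biogenesis genes were higher for 13 of 42 and lower for 0 (0.75, percentile 100), with SSF1 at 9.87 and 35.3 FPKM and NOP15 at 47.8 and 144. Ribosomal protein genes had a median of 0.71 (percentile 100), with 6 of 136 higher and 1 lower. Against the sap4 sap190 library, which also lacks SAP190, none of these 4 lists stood apart: the medians were 0.04 for general stress, 0.10 for heat shock, 0.01 for ribosome biogenesis (percentile 62.0) and 0.12 for ribosomal protein genes. On the same-sum scale, where all genes had a median of -0.48, ribosome biogenesis (0.18, with 1 of 42 higher) and ribosomal protein genes (0.12, with 0 of 136 higher) still stood apart on the high side.

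Iron regulon genes were lower for 12 of 24 and higher for 1 (-1.01, percentile 0), with FIT3 at 1567 and 131 FPKM and the siderophore transporter gene ARN1 at 186 and 32.9. Retrograde targets were lower for 3 of 7 and higher for 0 (-0.79, percentile 0.06), with CIT2 at 218 and 102 FPKM. Pdr1 and Pdr3 targets were lower for 3 of 14 and higher for 0 (-0.70, percentile 0.04), with PDR5 at 91.6 and 20.1 FPKM. The vacuolar protease and autophagy list (5 of 13 lower, -0.80), nitrogen catabolite repression targets (4 of 18 lower, -0.67) and TCA cycle genes (0 of 15 lower by 2-fold, -0.52) stood apart on the low side. Ergosterol genes did so as well with a median of -0.26. Against the sap4 sap190 library, retrograde targets (-0.05, percentile 34.7, with 1 of 7 higher and 0 lower), Pdr1 and Pdr3 targets (-0.01), TCA cycle (-0.08), vacuolar (-0.13) and ergosterol genes (0.10) no longer stood apart, while the iron regulon (-0.56) and nitrogen targets (-0.24) still did. The nitrogen list did not stand apart at a mean FPKM of at least 10 (-0.37 over 4 members, percentile 4.29). MATa-specific genes had a median of 0.48 (2 of 7 higher and 1 lower, percentile 98.6), which did not stand apart with a pseudocount of 5 (0.13) or at 300 nt or longer (0.19 over 4 members). Gcn4 targets had a median of 0.00 with 4 of 40 higher and 4 lower; the median lay at percentile 2.18, where matched lists had a median of 0.23, at percentile 2.68 with a mean FPKM of at least 10, and at -0.31 (percentile 0) against the sap4 sap190 library.

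Phosphate genes were higher for 7 of 17 and lower for 0 without standing apart (0.41, percentile 92.1). They did stand apart on the high side at a mean FPKM of at least 10 (0.81, percentile 99.99) and against the sap4 sap190 library (0.55, percentile 100), and their median was -0.18 on the same-sum scale (percentile 87.8). Named members were PHO5 at 38.8 and 248 FPKM and SPL2, a regulator of phosphate transport, at 308 and 1635. The fatty acid desaturase gene OLE1 was higher at 223 and 861 FPKM, and the acidic amino acid permease gene DIP5 was lower at 83.8 and 11.9. In all, 312 genes were higher and 309 lower, or 50.2% higher, against 8.60% on the same-sum scale, 35.2% on the upper-quartile scale, 45.5% with a pseudocount of 0.1 and 63.1% at a mean FPKM of at least 10. The authors' deposited table marked 21S_RRNA higher and SAP190, DDR2 and YJR005C-A lower.

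The sap4 sap190 comparison asks the same of the other pair. General stress genes were lower for 16 of 25 and higher for 0 (median -1.18, percentile 0), and heat shock genes for 9 of 19 with 0 higher (-0.89, percentile 0). HSP26 had 102 FPKM in the reference and 15.6 in the sap4 sap190 library, HSP78 had 16.1 and 1.83, HSP104 had 17.2 and 2.67 and HSP82 had 71.4 and 14.1. Ribosome biogenesis genes were higher for 15 of 42 and lower for 0 (0.78, percentile 100). NOP15 had 47.8 and 156 FPKM, SSF1 had 9.87 and 31.8, and RPF2, for a ribosome assembly factor, had 105 and 303. Ribosomal protein genes had a median of 0.55 (2 of 136 higher, 1 lower, percentile 100), and histone genes 0.71 with 0 of 10 members 2-fold apart (percentile 99.9). These 3 medians were 0.39 (4 of 42 higher and 1 lower), 0.15 (0 of 136 higher) and 0.31 on the same-sum scale and still stood apart.

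Retrograde targets were lower for 4 of 7 and higher for 0 (-1.08, percentile 0), with ACO1 at 713 and 337 FPKM and CIT1 at 58.1 and 18.9. Pdr1 and Pdr3 targets (2 of 14 lower, -0.69) and iron regulon genes (4 of 24 lower, -0.36) stood apart with 0 members higher, with PDR5 at 91.6 and 33.7 FPKM and FIT3 at 1567 and 522. TCA cycle (4 of 15 lower, -0.43), vacuolar protease and autophagy (5 of 13 lower and 1 higher, -0.68), oxygen-responsive (4 of 13 lower and 1 higher, -0.51), nitrogen catabolite repression (1 of 18 lower, -0.37), cell wall integrity (2 of 21 lower, -0.24), ergosterol (0 of 25, -0.26) and glycolysis genes (2 of 19 lower, -0.18) were also on the low side. Respiratory chain genes, with a median of -0.04, were there too (percentile 0.675). Mitochondrial ribosome genes stood apart on the high side at 0.33, and still did at -0.05 on the same-sum scale, where all genes had a median of -0.31, but not at a mean FPKM of at least 10 (percentile 95.3). The proteasome median was 0.00 at percentile 2.06, and it was -0.02, -0.39 and -0.17 with centring, the same-sum scale and the upper-quartile scale, on each of which the list stood apart on the low side. Cell wall integrity genes did not stand apart with a pseudocount of 5 (-0.09), the same-sum (-0.52) or the upper-quartile scale (-0.34), oxygen-responsive (percentile 25.6) and nitrogen genes (percentile 2.525) at a mean FPKM of at least 10, or respiratory chain genes at 300 nt or longer (percentile 4.92). In all, 245 genes were higher and 288 lower, or 46.0% higher, against 12.9% on the same-sum scale and 27.2% on the upper-quartile scale. Higher genes were the more numerous at a mean FPKM of at least 10 (57.9%) and with a pseudocount of 5 (50.8%). The authors' deposited table marked 0 genes higher and 4 lower: SAP4, SAP190, IGD1 and DAN1.

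The pph21 pph22 comparison asks what loss of the main PP2A catalytic subunits does. Cell wall integrity targets of Rlm1 were higher for 18 of 21 members, lower for 0 and neither for 3 (median 1.90, percentile 100). The cell wall glycoprotein gene SED1 (chromosome IV, 600793 to 601809) had 1192 FPKM in the reference and 48493 in the pph21 pph22 library, with bounds of 224 to 2145 and of 18180 to 78651. CWP1 had 19.4 and 1960 FPKM, and the wall protein gene CIS3 had 516 and 6898. Ace2 targets were higher for 6 of 11 and lower for 0 (1.29, percentile 100), including EGT2 at 9.33 and 57.4 FPKM. General stress genes were higher for 8 of 25 and lower for 0 (0.69, percentile 100), with HSP12 at 32.9 and 355 FPKM and HSP26 at 102 and 626. Heat shock genes had a median of 0.44 (2 of 19 higher and 1 lower). G1/S genes were higher for 5 of 22 and lower for 2 (0.36, percentile 99.3), with the G1 cyclin gene CLN2 at 5.87 and 31.7 FPKM. Ribosome biogenesis genes (8 of 42 higher, 0.60), glycolysis genes (5 of 19 higher and 1 lower, 0.45) and MATalpha-specific genes (2 of 4 higher, 0.80) also stood apart on the high side. Against the sap4 sap190 library, ribosome biogenesis (-0.20, percentile 60.3) and MATalpha-specific genes (0.28, percentile 92.0) no longer stood apart, while the general stress, heat shock and glycolysis medians were 1.82, 1.31 and 1.21. Glycolysis genes did not stand apart at a mean FPKM of at least 10 (0.41, percentile 97.4). Ribosome biogenesis and heat shock medians were 0.34 and 0.17 on the same-sum scale, where both lists still stood apart.

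Gcn4 targets were lower in the pph21 pph22 library for 34 of 40 and higher for 0 (-2.19, percentile 0). ARG1 had 853 and 21.2 FPKM, SNZ1 had 2269 and 19.96 and CPA2 had 210 and 6.78, beside HIS3, TRP1 and LEU2 transcripts that the reference listed at 0. Iron regulon genes were lower for 17 of 24 and higher for 0 (-1.34, percentile 0): FIT2 had 2057 and 21.7 FPKM, FIT3 had 1567 and 11.7 and the siderophore transporter gene SIT1 had 889 and 40.3. Phosphate genes were lower for 10 of 17 and higher for 0 (-1.69, percentile 0), with PHO84 at 2957 and 503 FPKM and SPL2 at 308 and 27.9. Retrograde targets were lower for 5 of 7 and higher for 0 (-1.56, percentile 0.045), with CIT2 at 218 and 46.3 FPKM and IDH1 at 676 and 179. This list had 3 of 7 lower and did not stand apart against the sap4 sap190 library (-0.69, percentile 17.3).

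Pdr1 and Pdr3 targets were lower for 5 of 14 and higher for 0 (-0.51, percentile 1.27), with PDR5 at 91.6 and 12.2 FPKM. The oxygen-responsive list had 4 of 13 lower and 1 higher (-0.70), and did not stand apart over the 12 members not listed at 0 in either library (-0.41, percentile 3.08). Subunits of the vacuolar proton pump, the V-ATPase, were lower for 6 of 16 and higher for 0 (-0.76, percentile 0.14), with VMA5 at 341 and 105 FPKM. Histone genes (-0.51) and mitochondrial ribosome genes (6 of 66 lower and 1 higher, -0.33) also stood apart on the low side. With the sap4 sap190 library in place of the reference, Pdr1 and Pdr3 targets (0.07), oxygen-responsive genes (0.17) and the V-ATPase (-0.73, percentile 6.18) no longer stood apart, and the histone and mitochondrial ribosome medians were -1.18 and -0.64. Pdr1 and Pdr3 targets also did not stand apart without an expression minimum (percentile 3.23), oxygen-responsive genes at a mean FPKM of at least 10 (percentile 4.14), or mitochondrial ribosome genes at 300 nt or longer (percentile 2.52). The IMP dehydrogenase gene IMD2 had 38.5 and 0.285 FPKM. In all, 443 genes were higher and 565 lower, or 43.9% higher. That share was 25.04% on the same-sum scale and 52.2% (540 higher and 494 lower) on the upper-quartile scale. The marker genes LEU2, marked higher, and LYS2, marked lower, were among the authors' calls. The authors' deposited table marked 5 genes higher, among them SED1, CWP1 and SRL3, and 17 lower, among them ARG1, SNZ1, FIT2, FIT3, ARN1, PPH21 and PPH22.

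**Figure D2:**
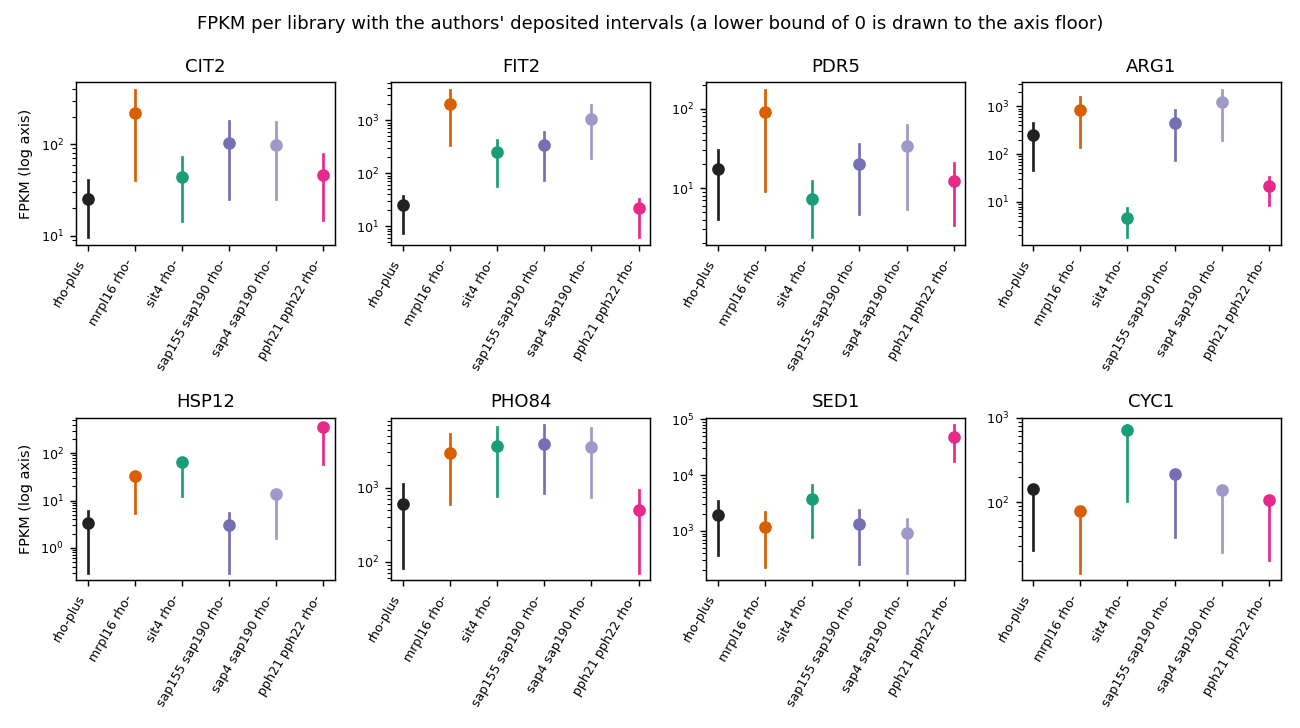
FPKM (log scale) of named genes in the 6 libraries, 1 library per strain; vertical lines are the confidence bounds deposited by the authors, which are not a spread between replicates. FIT2 lies at 2057 in the mrpl16 rho-minus reference, 25.1 in the rho-plus library and 21.7 in the pph21 pph22 library.

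The series also asks whether the phosphatase deletions move expression back towards the rho-plus level. Set against the rho-plus library, the retrograde list had a median of 2.47 in the reference, 0.76 in the library labelled sit4 rho-minus, 1.68 in the sap155 sap190 library, 1.39 in the sap4 sap190 library and 0.84 in the pph21 pph22 library. The iron regulon had 1.38 in the reference and 0.43, 0.40, 0.94 and -0.13 in these 4 libraries in the same order. Ribosomal protein genes had -1.43 in the reference and -1.05, -0.77, -0.89 and -1.26 in the other 4, but these values depended on the scale. On the same-sum scale they had -0.36 in the reference and -0.32, -0.30, -0.22 and -0.47 in the other 4, so that the pph21 pph22 library lay further from rho-plus than the reference. All genes had medians of 0.90 in the reference and 0.56, 0.41, 0.57 and 0.63 there. The retrograde list had 3.53, 1.46, 2.15, 2.05 and 1.60 in the same order on that scale, and the iron regulon 2.38, 1.04, 0.78, 1.52 and 0.59. Of the 639 higher and 443 lower genes of the mtDNA comparison, without deleted and mitochondrial genes, 76.5% differed from the reference in the direction of the rho-plus level in the sit4 library. The shares were 80.7% for sap155 sap190, 75.7% for sap4 sap190 and 69.6% for pph21 pph22. The higher genes had median folds of -0.50, -0.49, -0.32 and -0.59 in the 4 comparisons, and the lower genes 0.37, 0.69, 0.56 and 0.27.

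The reference enters both sides of this count, and simulated libraries without any effect gave 62.7% to 63.0%. Those simulations chose 800 higher and 614 lower genes on average, against 639 and 443 in the data, so they do not match its folds. Their share follows from the noise put in, and a larger noise would raise it. The excess over it is therefore no measure of a return. When the genes were chosen by comparing another phosphatase library with rho-plus, which leaves the reference out of the choice, the shares were 50.2% to 63.9% for sit4, 47.0% to 66.1% for sap155 sap190, 39.8% to 66.5% for sap4 sap190 and 48.0% to 63.5% for pph21 pph22. Simulated libraries without an effect gave about 50% then, with upper bounds of 52.5% to 52.8%. Those bounds are binomial intervals that count genes as independent, so they are too narrow for genes that vary together. The shares therefore depended on which library chose the genes, and the choosing libraries carry deletions of their own.

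**Figure D3:**
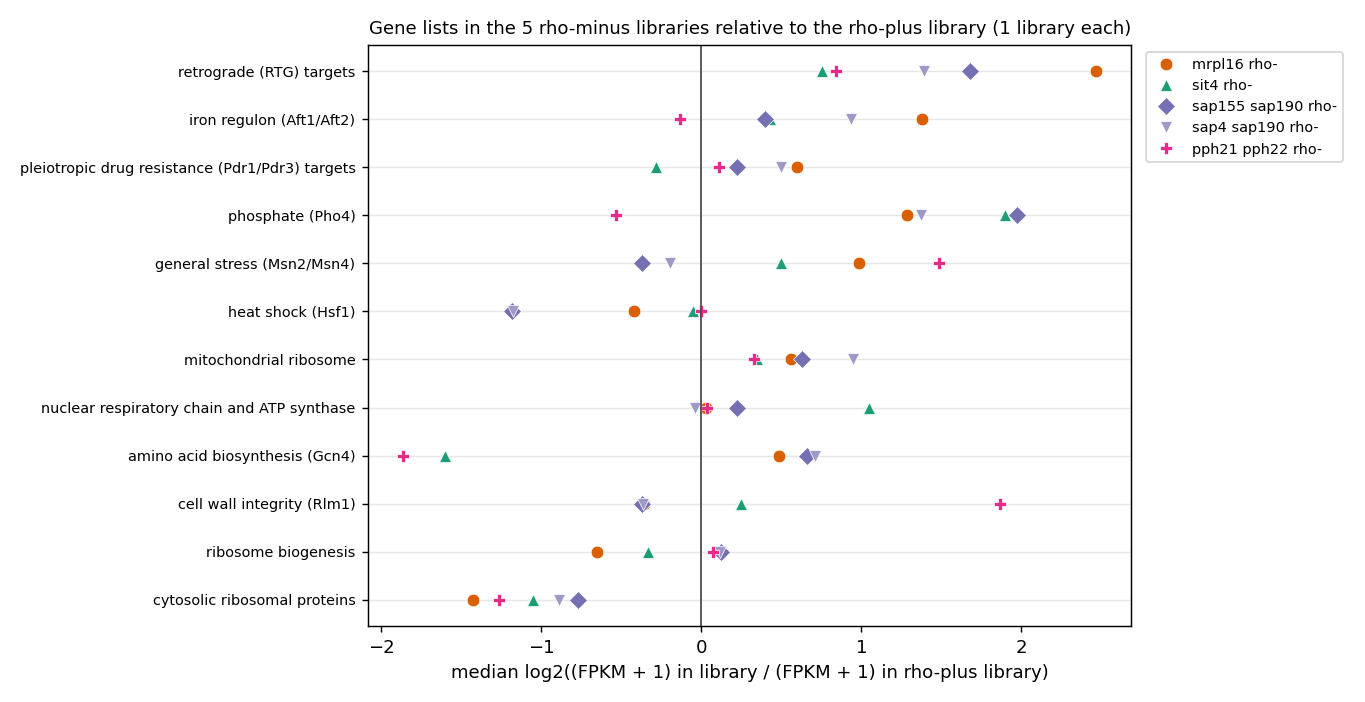
Median log2((FPKM + 1)/(FPKM + 1)) of 12 gene lists in each of the 5 libraries labelled rho-minus relative to the rho-plus library, 1 library per strain with no error bars. The retrograde list lies at 2.47 in the mrpl16 reference and at 0.76 to 1.68 in the phosphatase libraries; ribosome biogenesis genes, at -0.65 in the mrpl16 reference, lie at 0.31 on the same-sum scale, below the all-gene median of 0.90 there.

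Which of the deletions resemble each other was read from log2 folds across 5724 genes, which are not independent replicates. The sit4 and pph21 pph22 folds had r = 0.51 and a covariance of 0.510, with 96 genes higher and 219 lower in both and 42 in opposite directions. Independent lists of these sizes would share 21.2 and 39.4, and simulated libraries without an effect that share the reference shared 5.27 and 4.97. Of the Gcn4 targets 33 of 40, and of the iron regulon 10 of 24, were lower in both (ARG1 at 4.61 and 21.2 FPKM, FIT3 at 69.6 and 11.7), while PHO84 was at 3673 and 503. HIS3 was above 0 only in the sit4 and pph21 pph22 libraries (26.9 and 83.6 FPKM), so the Gcn4 overlap cannot be told apart from that strain marker. The iron overlap was not particular to this pair. It was 11 of 24 for sap155 sap190 with pph21 pph22, 9 for sit4 with sap155 sap190 and 4 for each pair with sap4 sap190. The sap155 sap190 and sap4 sap190 folds had r = 0.63 and a covariance of 0.497, with 135 genes higher and 137 lower in both and 14 in opposite directions. Independent lists would share 13.2 and 15.3, and the simulated libraries shared 5.20 and 4.88. The independent lists leave out the shared reference and the simulated libraries the effects, so the excess over either is not a measure of a shared effect. Of the heat shock genes 6 of 19 were lower in both, among them HSP104 (2.87 and 2.67 FPKM). The other pairs had r = 0.42 for sit4 and sap155 sap190, 0.39 for sit4 and sap4 sap190, 0.34 for sap155 sap190 and pph21 pph22 and 0.28 for sap4 sap190 and pph21 pph22.

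The reference library is shared by every pair, and simulated libraries without an effect gave r of 0.50 and a covariance of 0.077. Only the r of 0.63 between the sap190 deletions lay clearly above that value. It was 0.51 for sit4 with pph21 pph22 and lower for the other 4 pairs. The simulated r holds for libraries of like noise without effects. A noisier reference would raise r, and effects of 1 deletion alone would lower it, so r is no test of a shared effect either. The covariances of all 6 pairs, 0.257 to 0.510, exceeded the simulated one, and part of that excess may come from the shared library. The simulated covariance follows from the noise SD put in, 0.136 to 0.352 over the bins of mean expression. A larger noise would raise it, so the excess is no test of a shared effect. Among features of at least 300 nt the covariance was 0.340 for sit4 with pph21 pph22, 0.260 between the sap190 deletions, 0.168 for sit4 with sap155 sap190, 0.125 for sap155 sap190 with pph21 pph22, 0.0876 for sit4 with sap4 sap190 and 0.0802 for sap4 sap190 with pph21 pph22. A single reference library cannot be split. A second deletion library as the reference of one side does not solve this, because exchanging that library with the one it is subtracted from inverts the sign of r, so that such a value cannot show which pairs are alike.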

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

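The tests on rho-plus marker genes, on mitochondrial features, on the median of all genes and on the rho-plus library, and the choice of genes through the sit4 or pph21 pph22 library behind the shares of 50.2% and 48.0%, were chosen only after the result was seen. The sap4 sap190 library as reference and the disjoint choice of genes behind 47.0% and 39.8% were alternatives set before, though their use as tests was chosen after. The mitochondrial rRNA 21S_RRNA entered the counts of genes but none of the gene lists. It was above its level of 0 in the reference in the other 4 libraries labelled rho-minus. It had 16.1 FPKM in the sit4 library, 4.33 in the sap155 sap190 library, 0.834 in the pph21 pph22 library and 0.192 in the sap4 sap190 library. The last value is under the limit of 0.5 FPKM set for a signal. The rho-plus library had 13.3 FPKM. No group held 4 or more libraries, so no library was compared with others of its group.

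The mitochondrial transcripts of the library labelled sit4 rho-minus summed to 118% of the rho-plus level. RNA from the rho-plus culture would carry its other transcripts too, but STE2, BAR1, HMRA1 and MRPL16 lay at a median of 0.0697% of their rho-plus level there. Of the 10 mitochondrial features at 0.5 FPKM or more in the rho-plus library, 100% were so in the sit4 library, as mitochondrial DNA kept by those cells would give. These features are the rRNA genes, COX1 and features named for introns of COX1 and COB, so they do not speak for the whole mitochondrial genome. ATP6 and COX2, at 0.453 and 0.445 FPKM in the rho-plus library, were listed at 0 in the sit4 library. The hypothesis stays open, since it was found and tested on the same library, and the label and a later regain of mitochondrial DNA were not tested.

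The lower Gcn4 targets in the sit4 and pph21 pph22 libraries are the second pattern. A shift of the whole library would move the median of all genes by a like amount, but that median was -0.0105 for sit4 and -0.0254 for pph21 pph22. A reference library that was high by itself would leave the list near 0 against another library, but the medians against the sap4 sap190 library were -2.33 and -2.64. Strain markers cannot be told apart from the deletions: HIS3 was above 0 in these libraries alone, and against the rho-plus library, which also lists HIS3 at 0, the medians were -1.60 and -1.87, as either would give. The phosphatase deletions stay among the open explanations.

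The return of genes towards the rho-plus level cannot be told apart from the shared reference library. With genes chosen through another library, the lowest shares were 50.2% for sit4, 47.0% for sap155 sap190, 39.8% for sap4 sap190 and 48.0% for pph21 pph22, all under the simulated upper bounds of 52.5% to 52.8%. Other choosing libraries gave up to 66.5%, above those bounds. The bounds count genes as independent and are too narrow for genes that vary together, so a share on either side of them decides nothing. The choosing libraries carry deletions of their own, which may pull the share either way. That was not tested, and the question stays open.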

How the results depend on the processing

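Non-overlapping deposited intervals, the limit of at least 300 nt, the comparison without mating-type genes, the choice of genes through each other library, the same-sum and upper-quartile scales for gene lists and the comparison without features at 0 in either library were added after seeing the data; the other alternatives were set before. Where an alternative moved a value, the cause was not tested unless it is given.

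Under these settings at least 1 count of genes 2-fold apart, given as higher and lower, moved by more than 1.5 times. A pseudocount of 5, which shrinks the folds of low genes by construction, gave 321 and 338 for the mtDNA comparison, 172 and 229 for sit4, 187 and 144 for sap155 sap190, 121 and 117 for sap4 sap190 and 251 and 321 for pph21 pph22, and a pseudocount of 0.1 gave 487 lower for sap4 sap190. A mean FPKM of at least 10, which tests 2687 features, gave 308 and 368 for the mtDNA comparison, where lower genes then outnumber higher ones as with a pseudocount of 5, 170 and 217 for sit4, 224 and 131 for sap155 sap190, 158 and 115 for sap4 sap190 and 226 and 333 for pph21 pph22. Rescaling to the same sum gave 2508 and 63 for the mtDNA comparison, 170 and 674 for sit4, 93 and 989 for sap155 sap190, 99 and 671 for sap4 sap190 and 910 lower for pph21 pph22. The same upper quartile gave 149 and 399 for sap4 sap190; for pph21 pph22 it gave 540 and 494, both within 1.5 times, but the majority turned. The mean of the 5 libraries labelled rho-minus gave 298 lower for the mtDNA comparison. With the sap4 sap190 library as reference, 439 were higher for sit4, and 171 were higher and 164 lower for sap155 sap190. Genes of at least 300 nt whose deposited intervals did not overlap numbered 71 and 15 for the mtDNA comparison, 10 and 57 for sit4, 6 and 26 for sap155 sap190, 0 and 22 for sap4 sap190 and 33 and 90 for pph21 pph22. Of the planned settings, 23 counts of higher and 23 of lower genes stayed within 1.5 times, and leaving out mating-type genes gave 628 and 445 for the mtDNA comparison. Without features at 0 in either library the counts were 517 and 413, 240 and 340, 275 and 236, 198 and 222, and 405 and 472 in the 5 comparisons. In the authors' deposited table a q of at most 0.01 left 0 genes in each of the 5 comparisons, because the smallest q in it is 0.0223.

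Gene lists that stood apart changed to the other side of their matched random lists in 8 cases. The Gcn4 median of the mtDNA comparison was -0.26 with the mean of the 5 libraries labelled rho-minus. With the sap4 sap190 library as reference, ribosome biogenesis was -0.45 for sit4; ribosomal proteins were 0.12 (below their matched lists at 0.15), general stress 0.0379, heat shock 0.10 and ergosterol 0.10 for sap155 sap190; Pdr1 and Pdr3 targets were 0.0695 and oxygen-responsive genes 0.17 for pph21 pph22. Of the other list medians under the settings fixed beforehand, 449 still stood apart on the same side, 40 no longer stood apart, 42 newly did in the same direction and 8 newly did on the other side of their matched lists. Another 535 stood apart in neither setting, and 50 of these changed to the other side, 19 of them with the sap4 sap190 library as reference. At 300 nt or longer 83 still stood apart, 3 no longer did and 5 newly did. The numbers were 84, 2 and 3 on the same-sum scale, 85, 1 and 1 on the upper-quartile scale and 84, 2 and 3 without features at 0. Both scales move a list and its matched lists alike apart from the added 1, so they could change little. For named genes, 905 folds stayed on their side of 2-fold, 39 dropped below it and 16 passed it; summing values over the rows of a gene changes nothing, since each name has 1 row.

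The shares returning towards rho-plus moved with the library that chose the genes. The disjoint choice gave 63.9% for sit4, 47.0% for sap155 sap190, 39.8% for sap4 sap190 and 63.5% for pph21 pph22. Genes chosen with the sit4 library gave 62.1% for sap155 sap190, 66.5% for sap4 sap190 and 48.0% for pph21 pph22. Genes chosen with the sap155 sap190 library gave 58.6% for sit4 and 62.0% for pph21 pph22. Genes chosen with the pph21 pph22 library gave 50.2% for sit4, 66.1% for sap155 sap190 and 65.2% for sap4 sap190. A 4-fold threshold gave 71.5% for sit4, 76.8% for sap155 sap190 and 63.6% for pph21 pph22, and a pseudocount of 5 gave 79.6%, 83.2% and 78.7% for the first 3 deletions.

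The correlations of folds moved as well. With disjoint references the second fold is the difference between a pair of deletion libraries, and its sign follows which of them is called the reference. The values of equal size below are therefore 1 correlation with its sign inverted, and none of the 6 shows that a pair is alike or unlike. They were 0.0851 for sit4 with sap155 sap190, -0.0851 for sit4 with sap4 sap190, 0.19 for sit4 with pph21 pph22, 0.15 between the sap190 strains, -0.15 for sap155 sap190 with pph21 pph22 and -0.25 for sap4 sap190 with pph21 pph22. In the same order of pairs, a pseudocount of 5 gave 0.41, 0.33, 0.53, 0.66, 0.30 and 0.25, and features of at least 300 nt gave 0.36, 0.20, 0.52, 0.68, 0.22 and 0.15. A mean FPKM of at least 10 gave 0.38 for sit4 with sap4 sap190, 0.54 for sit4 with pph21 pph22, 0.36 for sap155 sap190 with pph21 pph22 and 0.30 for sap4 sap190 with pph21 pph22.

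No paired analysis was possible because each strain has 1 library. The depth is unknown, so the precision of a value can be read only from the deposited intervals. Those of HSP104 in the reference (6.06 to 28.4 FPKM) and in the sap155 sap190 library (1.24 to 4.56) do not overlap, while those of PDR5, with a higher FPKM, in the reference (9.09 to 174) and in the sit4 library (2.39 to 12.3) do.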

Other observations

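No test of an explanation was run in this part, and the genes in it were chosen after their values were seen. GCV1, GCV2 and GCV3, genes of the glycine cleavage system, which feeds carbon units to folate, were lower than in the reference in the sit4 and pph21 pph22 libraries. GCV1 had 159 FPKM in the reference, 9.70 in the library labelled sit4 rho-minus and 8.13 in the pph21 pph22 library. GCV2 had 14.3, 1.38 and 1.65 and GCV3 had 2437, 384 and 355. In the sap4 sap190 library the values were 153, 7.65 and 2188, so GCV2 was lower there too. SHM2, the cytosolic serine hydroxymethyltransferase gene, had 526 FPKM in the reference, 53.8 in the sit4 library and 231 in the pph21 pph22 library.

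PHO12 (552099 to 553502) and IMD2 (554396 to 555967) lie side by side near the right end of chromosome VIII. Both were near 0 in the pph21 pph22 library, at 0.683 and 0.285 FPKM, and had 29.7 to 204 and 21.5 to 60.1 in the other 5 libraries. PHO11, a near-identical copy of PHO12 on chromosome I, was listed at 0 in the pph21 pph22 library and had 7.34 to 82.2 FPKM elsewhere, so reads of the 2 copies cannot be separated. The oxidoreductase gene YHB1, which removes nitric oxide, had 427 FPKM in the reference, 2492 in the sit4 library and 158 in the pph21 pph22 library. OAC1, for a mitochondrial oxaloacetate carrier, had 75.4 FPKM in the reference, 9.76 in the sit4 library and 3.798 in the pph21 pph22 library. The Ty element genes YJR027W and YLR227W-B, which share sequence with other copies, had 34.9 and 32.8 FPKM in the pph21 pph22 library and 1.81 to 2.06 in the reference.

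Genes of the G2/M cluster, members of the Sit4 and PP2A complexes, glucose-repressed sugar genes, meiosis genes, methionine synthesis, peroxisome, unfolded protein response and zinc genes stood apart in none of the 5 comparisons at a pseudocount of 1 and a mean FPKM of at least 1. With the mean of the 5 libraries labelled rho-minus against rho-plus, methionine synthesis (-0.24), unfolded protein response (-0.36) and G2/M genes (-0.26) stood apart on the low side. The unfolded protein response also did in the mtDNA comparison with a pseudocount of 5, without an expression minimum, at 300 nt or longer and without features at 0 (percentiles 2.08 to 2.27), and methionine synthesis at a mean FPKM of at least 10 (-0.87 over 7 members). For sit4 the unfolded protein response stood apart on the high side without an expression minimum and at 300 nt or longer (percentiles 97.6 and 98.2). Glucose-repressed sugar genes stood apart at a mean FPKM of at least 10 for sit4 (1.14 over 4 members, percentile 99.94) and sap4 sap190 (-0.75 over 4 members, percentile 0.67). For pph21 pph22 they lay at percentile 97.4, and stood apart on the high side against the sap4 sap190 library (0.97, percentile 99.57), with a pseudocount of 5, on the upper-quartile scale, at 300 nt or longer and without features at 0. Peroxisome genes stood apart on the low side for pph21 pph22 with a pseudocount of 0.1 (-0.62, percentile 2.31). Glycolysis genes in the mtDNA comparison had a median of -0.42 at percentile 96.7, where matched random lists had a median of -0.80. Those matched lists can hold ribosomal protein genes, which were lower in that comparison. Glycolysis genes stood apart at a mean FPKM of at least 10 (percentile 98.5) and with the mean of the 5 libraries labelled rho-minus (percentile 98.7).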
